A study of Mus musculus with 8 samples.

How the data were processed

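The samples were 8 ATAC-seq libraries of progenitor B cells from mouse bone marrow, sorted as lineage-negative, B220-, CD19- and CD93-positive cells with positive to low CD43, per the labels. Their groups, Erg_control and Erg_knockout with 4 libraries each, were taken from the genotype labels. The submitters' processing notes name FastQC, STAR, MACS2, HOMER and DESeq2, without versions, and the build mm9. Which step each tool performed, how duplicates and mitochondrial reads were treated, whether insertion sites were shifted and whether peaks were called per library or on pooled reads are not given in the sources used here. Their effect on the counts could not be examined with the deposited files.

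The deposited table holds whole-number counts per peak and library, not normalized, in 52311 peaks. The same table gives the authors' log2 fold change and the authors' FDR, an adjusted p-value, for each peak, which are quoted only as the authors' deposited table. The deposited peak positions, given as chromosome, start and end, were identical in the count table and in the peak list for all 52311 peaks. Peak widths ranged from 83 to 2499 bp with a median of 459 bp. Peaks lay on 20 chromosomes, none of them Y, and the last peak of each ended within its mm9 length, while 8 ended past the GRCm38 length. All coordinates are those of the files, on mm9.

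Counts were analysed with edgeR 4.0.16 in R 4.3.3. Peaks were filtered with filterByExpr on the group (minimum count 10, minimum total 15), which left out 4966 and kept 47345. Libraries were scaled by TMM (factors 0.964 to 1.01), and a quasi-likelihood model with the group as its only term was fitted to all 8 libraries. Peaks with a Benjamini-Hochberg adjusted p below 0.05 are called. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values come from the edgeR cpm function with TMM-scaled library sizes, given as mean ± SD over 4 libraries. Counts per library ranged from 2129897 to 3944592, and the biological coefficient of variation was 9.35%. P-values of single peaks rest on the spread between these libraries, in part shared across peaks. Those of windows and of trends along a locus are computed over peaks and do not measure that spread.

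Sets of peaks were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the 6 receptor loci and, separately, over the gene lists with at least 4 tested peaks. Camera compares a set with all other peaks, whereas fry asks whether the peaks of a set move, in one direction or in either. Only the Tra/Trd locus passed camera, and it did not pass with an estimated correlation. Shares of counts per locus were compared by an exact two-sided permutation test over 70 assignments. Windows of 1 Mb with at least 5 tested peaks were tested by an exact two-sided hypergeometric test.

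No genome and no gene annotation of mm9 was used here. A gene table of assembly GRCm38.p6 served only for names, chromosomes and gene lengths, and none of its coordinates is printed. Peaks were therefore tied to genes only through 25 windows on mm9, 6 of antigen receptor loci and 19 of genes, which were written from general knowledge of the build before the data were examined. All 25 lay on the chromosome the gene table gives. Their lengths were 0.995 to 1.18 times that of the gene for all but 4, Rag1 with Rag2 (3.10), Id2 (2.62), Myc (1.59) and Spi1 (0.659). A peak said to be in a gene is a peak inside such a window, with no statement on exons, introns or promoters, and peaks just outside the windows are not counted. Bcl11b held 0 deposited peaks. Lists of pre-B-cell receptor and mature B-cell genes had no window and were not analysed here, nor were sequence motifs.

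The rule for named peaks was fixed before the data were examined, as were the tests of the planned comparisons, the lists and the alternatives listed below. It takes the 12 higher and 12 lower called peaks with the smallest p among those whose 4 knockout and 4 control CPM values do not overlap, the 3 peaks with the smallest p in each receptor locus and gene list (at most 1 per gene in a list), the tested Erg peaks, and up to 5 windows per direction.

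Replicates were compared first. Within groups, the Pearson correlation of log CPM over peaks was 0.935 to 0.967. The chi-square per degree of freedom between counts of a pair was 1.04 to 2.17. The lowest, between knockout replicates 1 and 2, lay close to the value of 1 that sampling noise alone gives (chi-square p = 1.95e-08). The next lowest was 1.30, and the pair of knockout replicates 1 and 2 also had the highest correlation. A value above 1 cannot exclude libraries made from the same cells. Every library was kept as a replicate, as the series describes them. The code was tested on simulated counts for the knockout against control comparison, drawn for 47345 peaks. It recovered 32.8% of 67 peaks changed 1.5-fold, 68.7% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 4 false calls. Over 90 set tests without change, 2 had a p below 0.05. These peaks were simulated independently, so this does not check camera for correlated peaks. In the simulation of changed peaks, changes below 2-fold were thus often missed. Far fewer peaks were changed there than the 6187 called in the data. The adjusted threshold was therefore stricter, and these rates need not hold for the data.

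Alternatives were other scalings (DESeq2 size factors, library totals, loess offsets), no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, leaving out each library, autosomes only, stricter thresholds, only peaks with a mean CPM above the median, an estimated camera correlation and 200 kb windows.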

Results

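Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in progenitor B cells sorted from the bone marrow of C57BL/6J mice. Erg is an ETS-family transcription factor with a known role in blood stem and progenitor cells. In the knockout group it was deleted in lymphoid cells by Cre recombinase under CD2 regulatory sequences acting on loxP-flanked Erg alleles. The control group carried the flanked alleles without Cre. Each group held 4 libraries, and the series describes them as biological replicates. The deposited table gave read counts in 52311 peaks on the mouse build mm9. Counts in peaks totalled 3944592, 3683138, 2129897 and 3657742 in control replicates 1 to 4, and 3796727, 3091966, 3424913 and 2904793 in knockout replicates 1 to 4. The shallowest library was thus a control. The first principal component of log2 CPM (counts scaled to the depth of each library) held 44.1% of the variance and had all 4 control libraries on one side and all 4 knockout libraries on the other.

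The Erg gene itself was examined first, because it was the targeted gene. All 17 deposited peaks in the Erg window on chromosome 16 (95606186 to 95807600) were tested, and 3 of them were more accessible in the knockout, while none was called lower. The 3 peaks lay at 95662823 to 95663189 (log2 fold change 0.65, SE 0.13, adjusted p = 0.000605), 95677415 to 95677916 (0.74, SE 0.14, adjusted p = 0.000222) and 95806884 to 95807600 (0.62, SE 0.13, adjusted p = 0.000594). The second of them rose from 16.9 ± 2.04 CPM in controls to 28.5 ± 0.762 CPM in knockouts (SD, n = 4 each). Log2 fold changes over the 17 peaks ranged from −0.40 to 0.74, with a median of 0.16. DESeq2 also called 3 peaks higher and 0 lower. One further peak, at 95657603 (0.51, SE 0.20, adjusted p = 0.0835), passed only without knockout replicate 1 (adjusted p = 0.0464). The share of all counts that fell in Erg peaks was 0.0464% ± 0.00229 in controls and 0.0542% ± 0.00237 in knockouts (SD, n = 4 each), with every knockout library above every control library (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow). The position of the deleted part of Erg was not used here, so these peaks do not check the genotype labels.

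The comparison that the design names asks which regions gained or lost accessibility without Erg. Of 47345 peaks tested, 2807 were higher and 3380 were lower in the knockout at an adjusted p below 0.05 (edgeR quasi-likelihood test), together 13.1%. Median log2 fold changes of the called peaks were 0.85 and −0.86. At least a 2-fold change was seen in 999 higher and 1288 lower peaks, and at least a 4-fold change in 79 higher and 229 lower peaks. The 4 knockout and the 4 control CPM values did not overlap in 2340 of the higher and 2663 of the lower peaks. Over all tested peaks, 15.2% had no overlap in either direction, where chance gives 2.86%. DESeq2 called fewer peaks, 1814 higher and 2367 lower. In the authors' deposited table, 2263 peaks were higher and 2754 were lower at a false discovery rate below 0.05.

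**Figure D1:**
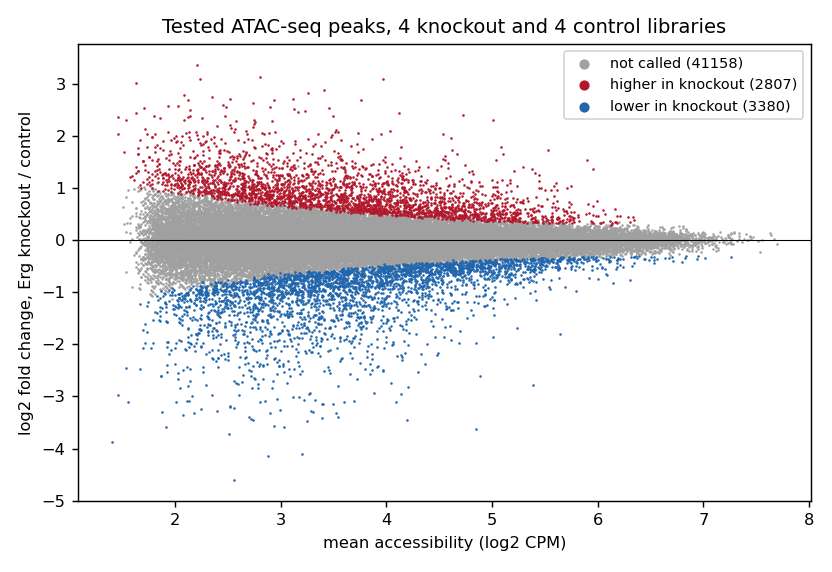
Each point is a tested peak, with its mean accessibility in log2 CPM on the horizontal axis and its log2 fold change, Erg knockout against control, on the vertical axis. The 2807 peaks called higher are red, the 3380 called lower are blue, and peaks that did not pass an adjusted p of 0.05 are grey.

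The peaks with the smallest p-values fell by up to 12.4-fold. The strongest evidence was for a peak on chromosome 18 at 47331924 to 47332833, which went from 73.1 ± 8.90 CPM in controls to 10.6 ± 0.684 CPM in knockouts (log2 fold change −2.77, SE 0.14, adjusted p = 7.01e-16). A second peak nearby, at 47329513 to 47329914, fell as well (−2.50, SE 0.20). On chromosome 11, a pair of peaks at 82223646 to 82224582 and 82235218 to 82235952 had log2 fold changes of −2.61 (SE 0.15) and −3.63 (SE 0.22), and the latter went from 52.7 ± 10.4 to 4.28 ± 2.05 CPM. Another pair on the same chromosome, at 71756962 to 71757538 and 71757821 to 71758405, changed by −1.97 (SE 0.15) and −2.20 (SE 0.17). The remaining lower peaks of this group of 12 were on chromosome 5 at 124682112 to 124683521 (−1.80) and 132319295 to 132320444 (−2.21), chromosome 17 at 35985067 to 35985635 (−3.45), chromosome 10 at 74470276 to 74471092 (−2.37), chromosome 8 at 15080494 to 15081196 (−2.96) and chromosome 11 at 59708604 to 59709254 (−2.30).

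Among peaks that gained accessibility, the smallest p-value belonged to chromosome 6 at 125102348 to 125103232, which rose from 8.08 ± 1.51 to 43.5 ± 4.79 CPM (log2 fold change 2.41, SE 0.16, adjusted p = 9.68e-13; SD, n = 4 each). It was followed by chromosome 4 at 136310039 to 136310684 (2.31, SE 0.15) and chromosome 11 at 35216968 to 35217586, which rose from 3.22 ± 0.943 to 26.7 ± 5.19 CPM (3.10, SE 0.22). Chromosome 5 held 3 of the 12, at 35508627 to 35509224 (2.45), 35986169 to 35987045 (1.73) and 36021592 to 36022703 (2.05). The others were on chromosome 2 at 167124652 to 167125977 (1.54), chromosome 11 at 32102214 to 32102700 (2.68), chromosome 6 at 101324638 to 101325298 (1.80), chromosome 7 at 144480754 to 144481666 (1.66) and 121324814 to 121325677 (1.54), and chromosome 10 at 122194962 to 122195827 (1.96). All 12 higher and all 12 lower peaks kept their calls under every alternative applied to single peaks. These were the other scalings, no filter, DESeq2, the replicate block, autosomes only and each left-out library. The stricter thresholds and the limit on mean CPM were not among them. The deposited files do not pair peaks with genes, so no gene is given for these positions.

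Accessibility of the immunoglobulin heavy chain locus is of particular interest because the series title concerns V-to-DJ recombination at Igh, the joining of a variable segment to an already joined diversity and joining segment. Of 79 tested Igh peaks on chromosome 12 (114456121 to 117238559), 5 were higher and 6 were lower in the knockout, the same counts adjusted over the list alone. No shift of the locus as a whole was detected: the median log2 fold change was −0.04 (camera adjusted p = 0.726), and it lay between −0.16 (without control replicate 4, adjusted p = 0.177) and −0.03 (without control replicate 2, adjusted p = 0.928) when 1 library was left out. A mixed-direction test of whether its peaks change at all passed (fry adjusted p = 4.44e-06). That test passed for every receptor locus but Trg, and 13.1% of all tested peaks were called, so this does not set Igh apart. Both of the largest increases lay close together. The peak at 114668626 to 114668933 rose from 2.42 ± 0.0937 to 8.95 ± 1.22 CPM (log2 fold change 1.88, SE 0.26, adjusted p = 2.51e-06), and the peak at 114685444 to 114685994 rose from 1.85 ± 0.948 to 8.65 ± 1.2 CPM (2.07, SE 0.29, adjusted p = 3.23e-06; SD, n = 4 each). The peak at 116261693 to 116262541 fell from 30.4 ± 2.18 to 18.8 ± 1.42 CPM (−0.68, SE 0.13, adjusted p = 0.000386). Igh peaks together held 0.110% ± 0.00377 of counts in controls and 0.106% ± 0.00577 in knockouts (SD, n = 4 each), a difference within the spread between libraries (exact two-sided permutation p = 0.400). Of the 11 Igh calls, 6 held under every alternative applied to single peaks, these 3 peaks among them.

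A few further Igh peaks were looked at after their values were seen. The peak at 114741236 to 114741551 was higher (log2 fold change 0.95, SE 0.28, adjusted p = 0.0175), a call that ended under DESeq2 (adjusted p = 0.111) and without control replicate 2 (adjusted p = 0.0748). Between it and the 2 strongest peaks, the peak at 114725867 to 114726190 had a log2 fold change of −0.05 (SE 0.25, adjusted p = 0.944). The peak at 117190653 to 117191087, at the far end of the locus, was lower (−1.19, SE 0.29, adjusted p = 0.00409).

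**Figure D2:**
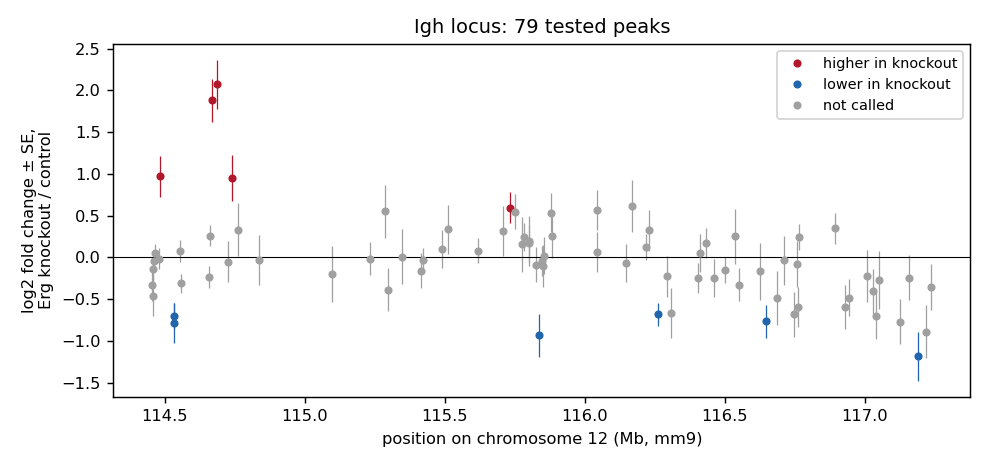
Log2 fold change, Erg knockout against control, with its SE as a bar, for the 79 tested peaks of the Igh locus along chromosome 12 (Mb, mm9). The 5 peaks called higher are red and include both peaks with a log2 fold change near 2, the 6 called lower are blue, and grey peaks were not called.

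In the T-cell receptor alpha and delta genes, which share a locus on chromosome 14, part of the peaks were more accessible in the knockout. Of 44 tested peaks (52915423 to 54879520), 11 were higher and 1 was lower, and 13 were higher and 1 was lower adjusted over the list alone. The median log2 fold change was 0.39, and 36 of the 44 estimates were positive (camera adjusted p = 8.81e-06). With an estimated correlation between peaks the shift no longer passed (camera adjusted p = 0.0946). Fry, which does not compare a set with other peaks, gave an adjusted p of 0.00351 for a shift upward. The locus held 0.0459% ± 0.00231 of counts in controls and 0.0552% ± 0.00156 in knockouts (SD, n = 4 each; exact two-sided permutation p = 0.0286, adjusted over the loci 0.0857). The peak with the smallest p, at 53983552 to 53984200, rose from 7.92 ± 2.09 to 20.9 ± 1.74 CPM (log2 fold change 1.35, SE 0.18, adjusted p = 1.34e-06; SD, n = 4 each). The peaks at 53914319 to 53914859 and 53965295 to 53965720 had log2 fold changes of 2.0 (SE 0.36) and 1.16 (SE 0.21). Measured in the same libraries, 12 peaks of the T-lineage regulators Gata3, Tcf7 and Notch1 had a median log2 fold change of −0.17, and edgeR called 0 of them (2 at an unadjusted p below 0.05), as did DESeq2.

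**Figure D3:**
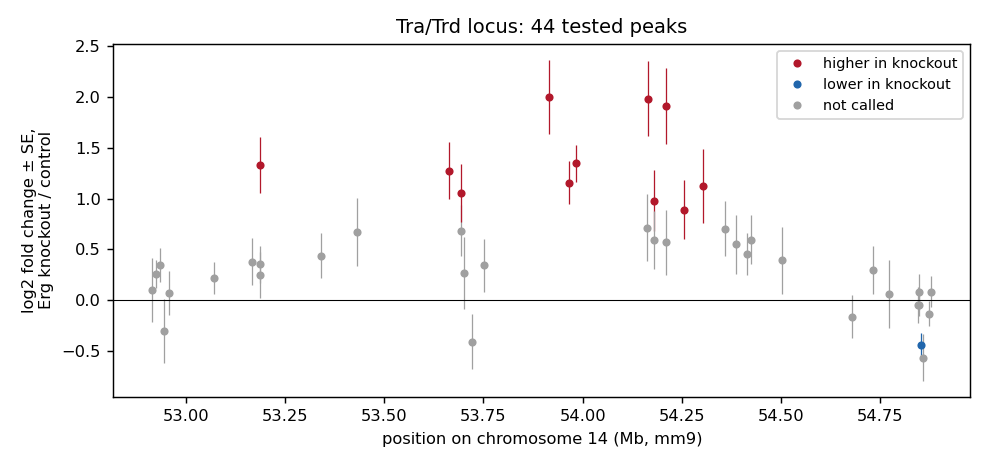
Log2 fold change, Erg knockout against control, with its SE as a bar, for the 44 tested peaks of the Tra/Trd locus along chromosome 14 (Mb, mm9). The 11 peaks called higher are red, the 1 called lower is blue and lies near the high-coordinate end, and grey peaks were not called.

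The other receptor loci had calls in both directions or none, and Trb resembled Tra/Trd in its median. In Igk, the kappa light chain locus on chromosome 6, 4 peaks were higher and 11 were lower among the tested of 154 deposited peaks, against 1 and 7 with DESeq2. The Igk median was −0.10 (camera adjusted p = 0.177, and 0.729 with an estimated correlation of 0.3). Its 3 peaks with the smallest p were all lower, at 70052887 to 70053483 (log2 fold change −1.20, SE 0.23), 69990510 to 69991380 (−0.60, SE 0.12) and 68700426 to 68700868 (−0.89, SE 0.18). At the preset correlation of 0.01, the Igk shift depended on single control libraries, since it passed without control replicate 2 (−0.23, adjusted p = 0.000988) and turned to 0.01 without control replicate 4 (adjusted p = 0.922). In Trb, the T-cell receptor beta locus, 2 of 10 peaks were higher and 2 were lower, and 5 were higher and 2 were lower adjusted over the list alone. The Trb median was 0.40, with 8 of 10 estimates positive (camera adjusted p = 0.117, but 0.0361 without control replicate 2), and fry gave an adjusted p of 0.0134 for a shift upward. Trb peaks held 0.0106% of counts in controls and 0.0131% in knockouts, with every knockout library above every control library (exact two-sided permutation p = 0.0286, adjusted over the loci 0.0857). There the peak at 40997090 to 40997627 was higher (0.96, SE 0.17) and the peak at 41203399 to 41203767 was lower (−1.55, SE 0.37). Another Trb peak, at 40971107 to 40971505, was higher (1.16, SE 0.32, adjusted p = 0.0101), but not under DESeq2 (adjusted p = 0.0806) or without knockout replicate 3 (adjusted p = 0.0686).

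In Igl, the lambda light chain locus on chromosome 16, 1 of 11 peaks was higher and 1 was lower, with a median of 0.04 (adjusted p = 0.688) that turned to −0.03 without control replicate 2 and −0.04 without knockout replicate 3. The higher one, at 19067110 to 19067356 (log2 fold change 1.14, SE 0.29, adjusted p = 0.00674), was no longer called without knockout replicate 3 (adjusted p = 0.0681). The lower one, at 19172293 to 19172636 (−1.03, SE 0.34, adjusted p = 0.0393), lost its call under DESeq2 (adjusted p = 0.189), with the replicate number as a block (adjusted p = 0.0682) and in every run that left out 1 library, except those without control replicate 3 or knockout replicate 4. Its adjusted p was 0.0943, 0.118 and 0.0697 without control replicates 1, 2 and 4, and 0.153, 0.133 and 0.12 without knockout replicates 1, 2 and 3. The peak at 19260402 to 19260809 had a value of 0.91 (SE 0.32, adjusted p = 0.0519), and passed without control replicate 4 (adjusted p = 0.0415) or knockout replicate 4 (adjusted p = 0.0449). In Trg, the T-cell receptor gamma locus on chromosome 13, edgeR and DESeq2 each called 0 of 10 peaks, and 1 had an unadjusted p below 0.05. Its 3 peaks with the smallest p had log2 fold changes of −0.38, −0.22 and 0.18. The Trg median of −0.02 turned to 0.03 without control replicate 2, 0.02 without knockout replicate 1 and 0.01 without knockout replicate 2.

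Called peaks in genes of B-lineage transcription factors were mostly lower in the knockout. Across Ebf1, Pax5, Ikzf1, Foxo1, Runx1, Spi1, Lef1, Irf4 and Irf8, 1 of 82 tested peaks was higher and 7 were lower, and 3 were higher and 10 were lower adjusted over the list alone. The median was −0.03 and no shift in one direction was detected (camera adjusted p = 0.374), while the mixed-direction test passed (fry adjusted p = 1.2e-04). That test passed for every list tested, and 13.1% of all tested peaks were called, so the list does not stand out. Runx1, a core-binding factor needed for early B-cell development, held 5 of the 7 lower peaks among 16 tested. The strongest, at 92727032 to 92727411 on chromosome 16, fell from 14.7 ± 2.12 to 5.29 ± 2.06 CPM (log2 fold change −1.51, SE 0.23, adjusted p = 7.88e-06; SD, n = 4 each). It held under every alternative applied to single peaks, as did the peak at 92715782 to 92716625 (−0.89, SE 0.16). The other 3 calls did not. The peak at 92620945 was not called without control replicate 2 (adjusted p = 0.0527). The peak at 92724754 was not called without control replicate 1 (0.0879) or knockout replicate 2 (0.0559), or under DESeq2 (0.0504). The peak at 92808004 was not called without control replicates 2 (0.112) or 3 (0.0604), or knockout replicates 1 (0.0773) or 3 (0.0645). The share of counts in Runx1 peaks was 0.0373% ± 0.00355 in controls and 0.0305% ± 0.00204 in knockouts (SD, n = 4 each; exact two-sided permutation p = 0.0286). Runx1 was singled out after its values were seen.

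In Ikzf1, which encodes the lymphoid zinc-finger factor Ikaros, the peak at 11616493 to 11617024 on chromosome 11 fell from 18.6 ± 3.5 to 7.97 ± 1.82 CPM (log2 fold change −1.27, SE 0.19, adjusted p = 1.12e-05; SD, n = 4 each), 1 of 11 tested. In Ebf1, which specifies the B lineage, the peak at 44438012 to 44438503 was higher (0.58, SE 0.15, adjusted p = 0.00780). Of 17 tested Ebf1 peaks, 1 was called higher and 1 lower, against 1 and 0 with DESeq2. In Pax5, which maintains B-cell identity, edgeR and DESeq2 each called 0 of 11 peaks, and 0 had an unadjusted p below 0.05. Log2 fold changes there ranged from −0.44 to 0.18.

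**Figure D4:**
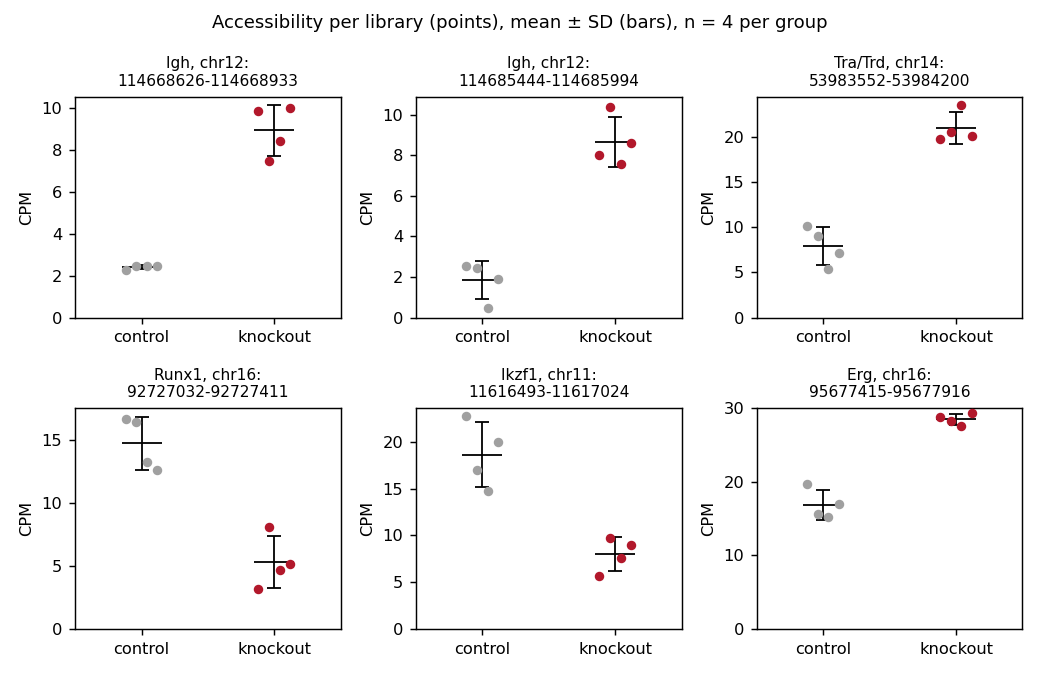
Accessibility in CPM of 6 peaks in each library (points), with the group mean and SD (bars), for 4 control and 4 knockout libraries. The Igh, Tra/Trd and Erg peaks are higher in every knockout library than in any control library, and the Runx1 and Ikzf1 peaks are lower.

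Genes of the recombination machinery had few called changes. Of 8 peaks in the windows of Rag1 and Rag2, which encode the recombinase, and of Dntt, which encodes the terminal transferase that adds bases at the joints, 0 were higher and 1 was lower, with a median of −0.06 (camera adjusted p = 0.601) that turned to 0.03 without control replicate 3 and 0.02 without control replicate 4. DESeq2 called 0 of the 8, and 2 had an unadjusted p below 0.05. The lower peak lay at 101468847 to 101469313 on chromosome 2 in the Rag1 and Rag2 window (log2 fold change −0.88, SE 0.28, adjusted p = 0.0288). It lost its call under DESeq2 (adjusted p = 0.102), with the replicate number as a block (adjusted p = 0.0539) and in every run that left out 1 library, except those without control replicates 3 or 4 or knockout replicate 4. Its adjusted p was 0.0565 and 0.220 without control replicates 1 and 2, and 0.0700, 0.0593 and 0.127 without knockout replicates 1, 2 and 3. The Dntt peak with the smallest p, at 41113517 to 41114243 on chromosome 19, had a value of −0.28 (SE 0.13, adjusted p = 0.171).

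Among the remaining fixed genes, the T-lineage list had a median of −0.17 over 12 peaks (camera adjusted p = 0.374). Its peaks with the smallest p were in Notch1 (log2 fold change −0.25, SE 0.12), Tcf7 (−0.22, SE 0.11) and Gata3 (−0.37, SE 0.20). The 1 peak of the interleukin-7 receptor gene Il7r had a value of 0.01 (SE 0.16; −0.05, −0.09 and −0.02 without control replicates 2 and 3 and knockout replicate 1), the peak with the smaller p of 2 in the proliferation regulator Myc 0.18 (SE 0.14), and the peak with the smaller p of 2 in Id2, a regulator of innate lymphoid cells, 0.05 (SE 0.10). Neither edgeR nor DESeq2 called any of these, and 0 had an unadjusted p below 0.05 in Il7r, Myc and Id2.

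Changed peaks were also counted in windows of 1 Mb, to see whether accessibility changed over domains. Of 1686 windows with at least 5 tested peaks, 28 held more higher peaks than the genome-wide share predicts and 14 held more lower peaks (exact hypergeometric test, adjusted p below 0.05), and no window was in both groups. On chromosome 11 from 18 to 19 Mb, 8 of 10 tested peaks were higher (adjusted p = 4.12e-05), and on chromosome 17 from 82 to 83 Mb, 8 of 11 (adjusted p = 7.16e-05). Next came chromosome 13 from 24 to 25 Mb with 16 of 63, chromosome 15 from 6 to 7 Mb with 8 of 15 and chromosome 3 from 50 to 51 Mb with 8 of 15. For lower peaks, the window with the smallest p was chromosome 5 from 132 to 133 Mb, where 7 of 8 were lower (adjusted p = 0.000158). It was followed by chromosome 16 from 89 to 90 Mb with 6 of 9, chromosome 2 from 146 to 147 Mb with 8 of 18, chromosome 7 from 124 to 125 Mb with 9 of 25 and chromosome 12 from 118 to 119 Mb with 8 of 21. The number of windows moved with the libraries used, and was 13 with more higher peaks without control replicate 1, 15 without control replicate 2, 18 without knockout replicate 1 or 2, and 16 without knockout replicate 3. For lower peaks it was 7 without control replicate 2, control replicate 4 or knockout replicate 2, and 8 without knockout replicate 1. With DESeq2, 11 windows had more higher peaks. The window test takes peaks as independent, and when the same number of peaks was taken, the 18 splits with 2 libraries of each genotype on both sides gave 0 to 43 windows, with a median of 4.5.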

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

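The tests of the Igh peaks, that of T-lineage genes and that of windows with equal numbers of peaks were chosen only after the result was seen. Of 182 sets of 4 library values examined, 18 (9.89%) held a library whose gap to its nearest neighbour took up an unusually large part of the range, where chance gives about 1 in 20.

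Total counts of control replicate 3 were 2129897, against 3657742 to 3944592 in the other controls (gap 0.842 of the range). Without this library, 2507 peaks were higher and 3186 were lower. In the Igl locus, control replicate 2 held 0.0156% of counts against 0.0177% to 0.0180% in the other controls (0.849), and in Tra/Trd control replicate 4 held 0.0424% against 0.0466% to 0.0474% (0.838).

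Among peaks with the smallest p, control replicate 2 stood at 7.13 CPM against 4.39 to 4.55 on chromosome 5 at 35508627 (0.939) and at 17.3 against 16.2 CPM in the others on chromosome 7 at 121324814 (0.979). Knockout replicate 3 stood apart in that chromosome 7 peak, with 52.8 CPM against 46.0 to 46.8 (0.884), and in the peak on chromosome 6 at 101324638, with 41.8 against 54.3 to 56.2 CPM (0.866). Knockout replicate 2 had 5.85 CPM against 3.19 to 3.45 on chromosome 8 at 15080494 (0.903). None of these values reached those of the opposite group, which the rule that named these peaks requires.

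In receptor loci, control replicate 1 had 2.28 CPM against 2.45 to 2.47 in the Igh peak at 114668626 (0.927), a gap within a very narrow range. Knockout replicate 3 had 16.8 CPM against 7.80 to 9.32 in the Igh peak at 114483009 (0.832), whose call was lost without it (adjusted p = 0.0830), and 9.00 against 4.55 to 5.08 CPM in the Igk peak at 70052887 (0.881). Control replicate 4 had 11 CPM against 14.4 to 15.1 in the Igh peak at 116645628 (0.838) and 14.8 against 9.32 to 9.87 CPM in the Trb peak at 40997090 (0.900). In the Igl peak at 19172293, knockout replicate 4 had 4.49 CPM against 1.60 to 1.74 (0.952).

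In gene windows, control replicate 1 had 27.8 CPM against 17.0 to 18.6 in the Ebf1 peak at 44438012 (0.849), and 12.6 against 8.22 to 8.34 CPM in the Runx1 peak at 92724754 (0.973), whose call was lost without it (adjusted p = 0.0879). In Erg, knockout replicate 3 had 16 CPM against 9.09 to 9.66 at 95606837 (0.917), and control replicate 3 had 25 CPM against 19.7 to 20.6 at 95680981 (0.843).

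The number of called peaks was set against all 35 splits of the 8 libraries into 4 and 4. Only 1 split, the real one with 6187 calls, reached that number, and the highest of the others called 1 peak, which argues against a chance split of the libraries. For 1 Mb windows with an excess of called peaks, 1 of 35 splits, the real one, reached the 42 windows and the highest other count was 0, but this decides nothing, since the other splits called too few peaks to fill a window. When each split took its 6187 peaks with the smallest p, 2 of 35 splits gave at least 42 windows, the other giving 43, so chance cannot be excluded for the number of windows by this count. Most splits lay far lower, with a median of 4.5 windows over the 18 splits with 2 libraries of each genotype on both sides and 4 to 20 windows with 1 library exchanged. The split with 43 set control replicates 1 and 3 and knockout replicates 2 and 3 against the other 4 libraries.

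The first pattern to weigh is the rise of 3 Igh peaks at 114668626, 114685444 and 114741236. If V-to-DJ joining in control cells had deleted the DNA out to distant V segments, the next peaks on the V side would rise about as much. From 114762873 to 115491561, the median log2 fold change of those 10 was −0.0235. Its SE of 0.11 comes from the spread over the 10 peaks, taken as independent, and not from the libraries. The 3 that rose had at least 0.95, but they were picked for being called higher, without the uncalled peak among them. That the 10 did not rise as a group argues against deletion reaching past them as the whole cause. Deletion that ends at a nearer V segment would spare most of them, so it stays open. The lowest log2 fold change of the 2 strongest peaks over 4 scalings of the libraries was 1.87, but these scalings moved each peak by at most 0.0210 and so decide nothing. Fewer alleles with a D-to-J deletion in the knockout sorts could raise peaks between these segments, and this stays open, because the peak among them with a value of −0.0511 cannot be placed inside or outside the D segments without an annotation of mm9. A change of chromatin through loss of Erg also stays open, as it follows the groups and was not tested separately.

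The second pattern is the rise over Tra/Trd. A rise of all weak peaks in the knockout is argued against. Of 10000 lists of 44 peaks matched on mean CPM, 0 had as high a median. Of 46485 runs of 44 neighbouring peaks, only 0.131% had one, although runs outside the locus reached 0.68. These runs were not matched on CPM, and the matched lists were drawn as single peaks, not as neighbours. Regional drift of weak peaks therefore stays open. Over the 35 splits of the libraries, 1, the real one, had a median as far from 0 as 0.39, and the highest of the others was 0.31. For this locus taken alone, this argues against a chance split. However, 1 of 35 is the least this count allows, and it was not adjusted over the 6 receptor loci. The exact permutation p of the locus share, 0.0286, became 0.0857 with that adjustment. T-lineage cells in the knockout sorts may still contribute: 12 peaks of Gata3, Tcf7 and Notch1 had a median of −0.17, but their median control level of 18.8 CPM, against 5.11 CPM for Tra/Trd peaks, would hide a small share of T cells, and the CD19 and lineage gates should remove such cells. An effect of the genotype on the locus stays open too.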

How the results depend on the processing

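Every alternative named here was fixed before the data were examined. No peak called here was called in the opposite direction under any other scaling, filter, test, block or left-out library. Peaks that lost their call were not all checked for direction. DESeq2 size factors, library totals, loess offsets, no filter and autosomes only kept 97.4% to 99.6% of the 6187 calls. With the DESeq2 Wald test, 1814 peaks were higher and 11 windows had more higher peaks, and 66.2% of calls were shared. At an adjusted p below 0.01, 3861 peaks were called, 1699 higher and 2162 lower. With a log2 fold change of at least 1, 2287 were called, 999 higher and 1288 lower, and among peaks with a mean CPM above the median 2520, 1111 higher and 1409 lower. These follow from stricter limits or fewer peaks, and for DESeq2 the cause was not tested. With 200 kb windows, 9 had more lower peaks (the cause was not tested). The Tra/Trd median of 0.39 had an adjusted p of 0.0946 with an estimated correlation, since a higher correlation widens the test.

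Leaving out 1 library at a time, calls ranged from 5038 to 6576, 2225 to 3078 higher and 2643 to 3498 lower. Windows with more higher peaks ranged from 13 to 26 and with more lower peaks from 7 to 14. Locus medians ranged from −0.156 to −0.0263 for Igh, −0.229 to 0.0138 for Igk, −0.03997 to 0.13 for Igl, 0.35 to 0.56 for Tra/Trd (adjusted p at most 0.000315), 0.33 to 0.48 for Trb, −0.0727 to 0.0311 for Trg and −0.16 to 0.0295 for the recombination genes. Signs turned only near 0, and beyond fewer samples the cause was not tested. Of single peaks not called, the Erg peak at 95649760 turned from −0.01 to 0.00610 with library totals and 0.00241 with loess offsets, and ranged from −0.0603 to 0.0719 without single libraries. The Erg peaks at 95696185 and 95792193 ranged from −0.18 to 0.19 and −0.17 to 0.0333, and the Il7r peak from −0.0931 to 0.10.

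With the replicate number as a block, 2451 peaks were higher and 2954 lower, and 86.3% of calls were shared. The labels do not say that libraries of equal number share a litter or a day. Deviations from the group means correlated between same-numbered libraries at −0.188, 0.154, −0.149 and −0.0555, and only number 2 correlated best with its own number, so the numbers were not taken as pairs. Planned assignments of peaks to start sites within 10 kb and 1 kb and both motif alternatives were not run, since they need an annotation or a genome of mm9. At the depth, replication and spread of these libraries, simulated 1.5-fold changes were recovered in 32.8% of 67 peaks. The simulation changed far fewer peaks than were called in the data.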

Other observations

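All trends, bins and neighbour comparisons here were chosen after the data were seen, apart from the test on mixed splits, whose bound was set before it was run.

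Along the kappa light chain locus Igk, the log2 fold change fell with the coordinate. Spearman's rho over the tested peaks of the locus was −0.398 (Pearson r −0.355; permutation p = 2e-05, adjusted over the 2 loci examined 4e-05), and −0.376 over the 100 peaks that were not called. It stayed between −0.454 and −0.278 without any single bin of 0.5 Mb and between −0.414 and −0.328 without any single library. From 69.5 to 70 Mb, 13 of 14 estimates were negative, and from 70 to 70.5 Mb 17 of 19, with 2 and 5 peaks called lower. From 67.5 to 68 Mb, 14 of 20 were positive. Summed over these bins, CPM in knockouts was 0.781, 0.735 and 1.06 times that in controls, and none of these bins passed an exact permutation test (p = 0.0571, 0.114 and 0.571). Peaks of one locus are not independent replicates, and neighbouring peaks changed together. The p-values of the trend come from shuffling peaks freely, so they can be too small, here and for Igh below. They do not measure the spread between libraries, and no test between libraries was made of either trend.

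In Igh the same measure gave rho −0.349 over 79 peaks (Pearson r −0.378; permutation p = 0.00198, adjusted 0.00198), and −0.337 over the 68 that were not called. All 9 tested peaks from 117 to 117.5 Mb, the end of the locus away from the constant-region genes, had negative estimates with a median of −0.41, and 1 of them was called, but their summed CPM, 0.671 times that in controls, did not pass an exact permutation test (p = 0.114). Of the other Igh bins, summed CPM was 1.11 times that in controls in the 4th from the low-coordinate end, where 12 of 16 estimates were positive, and 0.868 times from 116.5 to 117 Mb (exact permutation p = 0.0286 in both, adjusted over 20 bins 0.0952). The Igh trend rested on this end and on a single control: rho was −0.163 without that bin (p = 0.177), −0.243 without the bin from 116.5 to 117 Mb (p = 0.0518) and −0.188 without control replicate 2 (p = 0.0954).

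In Tra/Trd, summed CPM was higher in the knockout in the 4 bins from 52.5 to 54.5 Mb (exact permutation p = 0.0286 in each, adjusted over 20 bins 0.0952), and no test compared the bins. It was 1.16 times that in controls from 52.5 to 53 Mb and 1.34 times from 53 to 53.5 Mb, where 7 of 7 estimates were positive. From 53.5 to 54 Mb, 5 of 9 peaks were called higher and summed CPM rose from 39.6 ± 8.02 to 74.6 ± 6.09, and from 54 to 54.5 Mb 5 of 12 were, with all 12 estimates positive and a rise from 45.2 ± 9.41 to 76.1 ± 9.20 CPM (SD, n = 4 each). From 54.5 to 55 Mb, 0 of 11 were higher and 1 was lower with edgeR, and the summed CPM was 0.913 times that in controls.

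Called peaks were least common among the most accessible peaks. Ranked by mean CPM into 4 groups of equal size, 13.2%, 16.4%, 15% and 7.64% were called from the lowest to the highest. On the X chromosome, 67 of 878 tested peaks were called, 32 higher and 35 lower.

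Neighbouring peaks changed together. The Pearson correlation of log2 fold change between adjacent peaks, across peaks, was 0.523 under 1 kb (4803 pairs), 0.266 from 1 to 10 kb, 0.204 from 10 to 100 kb (22643 pairs) and 0.141 from 100 kb to 1 Mb. Of 648 adjacent pairs that were 10 to 100 kb apart and both called, 551 (85.0%) changed in the same direction. Regional differences between libraries unrelated to the genotype are a candidate explanation, but 0 of the 18 splits with 2 knockout and 2 control libraries on each side gave as large a covariance at 10 to 100 kb, and the highest of them was 0.00739 against 0.0466 for the real groups. The spread of the real log2 fold changes alone gave at most 0.00497 over 1000 shuffles of their positions. On the scale of the correlation, looked at after the values were seen, these 18 splits ranged from 0.0461 to 0.183 with a median of 0.0911, against 0.204 for the real groups, and splits with 1 library exchanged reached 0.180. Neighbours thus also moved together without the genotype, to a smaller extent.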
